A study of Mus musculus with 15 samples.

How the data were processed

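RNA of mouse cardiac fibroblasts was sequenced in 15 libraries, in 5 groups of 3 given by the labels. Per the labels' protocols the cells came from the infarct region of C57BL/6 hearts at day 6 after infarction, RNA was extracted with TRIzol and the Direct-Zol kit, and a sequencing provider made the libraries. The aligner, the counting tool, strandedness and read length are not given in the sources used here. The build, mm10 (GRCm38), is stated per the submitters' processing notes. The deposited values are FPKM, fragments per kilobase of gene length scaled to a library total, that the authors computed for 54532 genes with the gene length beside each. Multiplying each value by its gene length gave whole multiples of 1 step per library in 100% of values, within 0.01 reads, so whole reads per gene and per library could be recovered. The library total that the authors divided by was on average 1.01 times the sum of those reads (geometric mean), with a different ratio per library, as a scaled library size gives. Coordinates are those of the deposited table. Of its genes, 54495 are in GENCODE mouse release M21, 53585 with the same start and end, and GC content was available for 99.8%. As strandedness is not given, reads of a gene and of one on the other strand cannot be told apart where exons overlap. Values are uncertain for this reason in Mest (Copg2), Ndufa4l2 (Shmt2), Mfap4 (Mapk7), Fabp3 (Zcchc17), Myom1 (Myl12a), Col10a1 (Nt5dc1), Myh1 (Myhas) and Myh7 (Mhrt). They are also uncertain in Sall4, Myh6, Myh2, Myl4, Des, Mylk, Slc8a1, Mcam, F13a1, Thbs1, Pdgfra, Cdkn1a, Ptprn, Serpinb9b, Clca3a1 and Nkain4, over unnamed antisense transcripts. The same holds for Spp1, Itga10, mt-Nd4, mt-Nd2 and mt-Atp6, whose exons overlap others on their own strand, and for near-identical families (the actins, the skeletal and cardiac myosin heavy chains, the Serpinb genes, the Ifit genes and Hspa1b with Hspa1a).

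Tests were run with limma 3.58.1 in R 4.3.3, and tables and plots with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The main test was limma (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1), a mean per group over all 15 libraries, with 10 residual degrees of freedom. Genes with an FPKM of at least 1 in at least 3 libraries were tested, 13856 of 54532. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Log2 changes are differences of group means of log2(FPKM + 1), which shrinks the change of genes near an FPKM of 1 or below. Values are given as mean FPKM ± SD with n = 3 libraries per group. Where a gene was at 0 in all 3 libraries of a group it is described as listed at 0 and given no fold. The comparisons were shCalr against shNT at day 7 and at day 14, the difference between these (interaction), each infected group against day 0, and day 14 against day 7 within each hairpin.

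In all, 27 gene lists were fixed. They cover the 5 factors, sarcomere, calcium handling and excitation, cardiac regulators, fibroblast and matrix genes, TGF-beta and myofibroblast genes, chaperones of the endoplasmic reticulum, the integrated stress response, store-operated calcium entry and NFAT, inflammation, interferon response, cell cycle, p53 and senescence, fatty acid oxidation and mitochondria, glycolysis, and mitochondrially encoded mRNA. Marker lists cover skeletal muscle, smooth muscle, pericytes, macrophages, other leukocytes, endothelium, epicardium, Schwann cells, adipocytes, cartilage and bone, and erythroid cells. The lists with at least 5 tested members, 22 of them, were compared with all other genes by limma's camera with a preset correlation of 0.01 and adjusted over the 22 lists. Each list call was repeated with a correlation estimated per list. Where a call of the main fit is printed without that value, it stayed under 0.05. Its adjusted p was then larger than the one printed, often by orders of magnitude. The other leukocyte, Schwann cell and erythroid lists had 0 tested members. The adipocyte list had 3 and the cartilage and bone list 4, so neither was tested as a list. The smooth muscle list shares Acta2, Cnn1, Tagln and Myl9 with the TGF-beta list, and many of the smooth muscle, skeletal muscle and epicardial markers are also expressed in fibroblasts or cardiomyocytes.

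Named genes followed a rule. Calr and the 5 factors are named whatever their values. In shCalr against shNT and in shNT against day 0, the 10 called genes with the largest change each way are named if all 3 libraries of one group lay above all 3 of the other, the higher group had a mean FPKM of 2 or more and the symbol was not a predicted gene. Any single gene meets the condition on the libraries by chance in a share of 0.1 of the splits of 6 libraries. In the other comparisons the top 3 each way are named. Up to 4 members with the smallest p are named from each called list or marker list of another cell type. Genes named outside the rule are said to be.

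The lists, the rule, the tests and most alternatives were fixed before the data were examined. The alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, rescaling to TPM, median-ratio scaling, quantile normalization, the replicate number as a block, limma without a trend and with robust variances, limma-voom on the recovered reads, only the libraries of the contrast, leaving out each library in turn, and a fold change of at least 2. For lists they included the estimated correlation and fry, which tests whether a list moves one way without comparing it with other genes. A GC correction (lowess with a span of 0.3) and leaving out 5 libraries, the one of each group farthest from its group's median GC slope, were added after seeing the data. The GC slope of a library is the change in log2(FPKM + 1), relative to the gene's mean over the 15 libraries, per 10 percentage points of GC. No pairing by replicate number was seen. The labels do not state any, and structure between libraries could hide it. After subtracting group means, same-numbered libraries of different groups correlated between -0.67 and 0.59 across genes, no pair of groups had all its correlations over 0.1, and 4 of 15 libraries correlated best with their own number.

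The depth was 9505879 to 12791001 recovered reads per library, and 1 read on a gene of 1 kilobase is an FPKM near 0.1. The same test was tested on simulated data of the 13856 genes with 200 of them changed. The changed genes were drawn from those with a mean FPKM of 2 or more in the shNT group of that day. The rates therefore do not cover genes below that level. At day 7 it called 8.96% of genes changed by 1.5-fold, 49.3% of those changed by 2-fold and 86.4% of those changed by 4-fold, and 4% of its calls were unchanged genes. At day 14 the values were 7.46%, 47.8%, 83.3% and 5.15%. The simulation drew each gene on its own, with the same spread setting in all groups. It holds neither a spread that differs between groups nor a structure shared across genes, so its rates may not hold for these libraries. The labels do not say whether the 3 libraries of a group are separate animals, cultures or wells. All p-values here measure only the spread between these libraries, which may be technical. No 2 libraries of a group were duplicates, since counts of each pair differed by more than Poisson sampling (chi-square per gene 3.27 to 204).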

Results

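Gene expression was profiled by bulk RNA sequencing in cultured cardiac fibroblasts from infarcted hearts of male C57BL/6 mice. The 15 libraries form 5 groups of 3. One group is the fibroblasts at day 0. The other 4 groups received the cardiac transcription factors Mef2c, Gata4, Tbx5 and Myocd and the zinc finger factor Sall4, introduced to turn fibroblasts towards cardiomyocytes. With them came a hairpin against Calr (shCalr) or a non-targeting hairpin (shNT), and cells were sampled at day 7 or day 14. Calr encodes calreticulin, a calcium-binding chaperone of the endoplasmic reticulum. The reads assigned to genes numbered 10366674, 10607310 and 9505879 in day 0 replicates 1, 2 and 3. At day 7 they numbered 12410350, 12271146 and 10368057 in shNT and 10999106, 10812036 and 11057016 in shCalr. At day 14 they numbered 10170991, 10813785 and 10177582 in shNT and 12791001, 10758248 and 10664275 in shCalr. Members of gene lists are counted as called higher or lower by limma, and the members not counted in either were tested and not called. The first principal component of the tested genes held 53.7% of the variance and the second 12.8%. Day 0 scored from -98.1 to -52.8 on the first, and shNT day 7 replicate 3 stood at -39.5, apart from the other infected libraries at 9.69 to 41.1.

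Libraries of one group differed in the share of reads on mitochondrially encoded genes. That share was 4.26, 1.30 and 3.39% in day 0 replicates 1, 2 and 3, 0.895, 0.816 and 4.37% in shNT day 7, and 0.119, 2.57 and 2.32% in shCalr day 7. At day 14 it was 0.198, 0.296 and 0.261% in shNT and 2.49, 0.369 and 0.553% in shCalr. The group means were 2.99 ± 1.52% at day 0, 2.03 ± 2.03% in shNT day 7, 1.67 ± 1.35% in shCalr day 7, 0.252 ± 0.0494% in shNT day 14 and 1.14 ± 1.17% in shCalr day 14. The GC slope, the trend of a library's expression with GC content in log2 per 10 percentage points, also varied. It was -0.63, -0.01 and -0.64 in the day 0 libraries, 0.48, 0.12 and -0.62 in shNT day 7, 0.27, 0.03 and 0.07 in shCalr day 7, 0.20, 0.12 and 0.16 in shNT day 14, and 0.10, 0.18 and 0.17 in shCalr day 14.

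**Figure D1:**
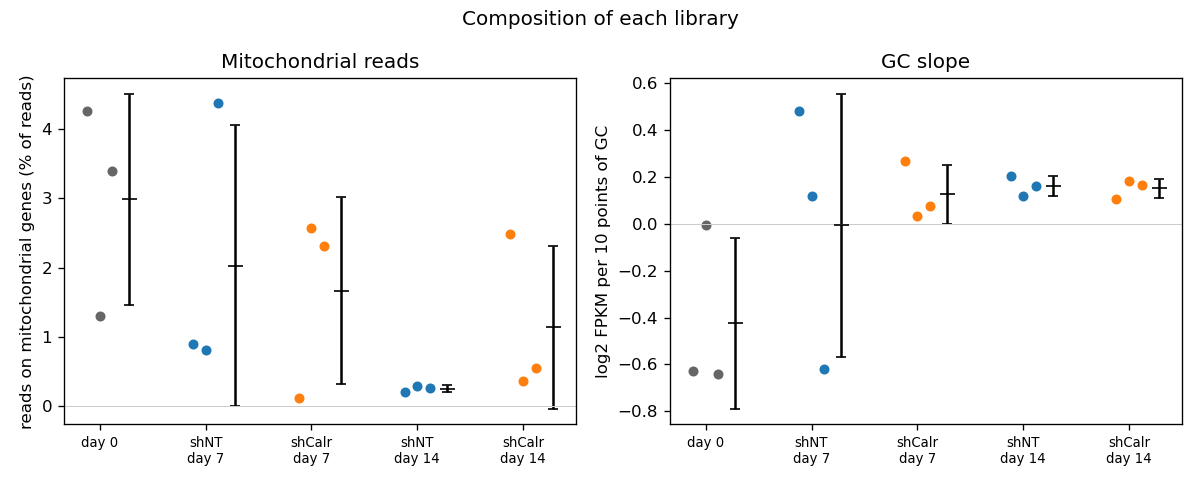
Share of reads on mitochondrially encoded genes (percent) and GC slope (log2 per 10 percentage points of GC) of each library, by group. Points are libraries and black bars the mean ± SD of 3. The mitochondrial share spans 0.119 to 4.37%, and shNT day 7 replicate 3 lies with day 0 replicates 1 and 3 in both measures.

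Calr, the target of the knockdown, was lower in every shCalr library than in every shNT library of its day. Its FPKM was 76.5, 97.5 and 87.7 in the shCalr day 7 libraries against 320.4, 264 and 310.0 in shNT day 7, and 68.9, 59.8 and 64.8 against 216, 212 and 215 at day 14. Day 0 libraries had 400.2, 360.1 and 389.9. The change was -1.76 on the log2 scale at day 7 (means 87.2 ± 10.5 and 298 ± 30.1, adjusted p = 1.8e-05). At day 14 it was -1.72 (64.5 ± 4.55 and 214 ± 2.19, adjusted p = 1.1e-05), and the difference between the days was not called (0.04, adjusted p = 0.993). Calr was also lower at day 14 in cells given the factors and shNT (-0.84 against 383 ± 20.8 at day 0, adjusted p = 0.000386). At day 7 shNT stood at -0.37 from day 0 and was not called (adjusted p = 0.0727). Calr is ENSMUSG00000003814, a protein-coding gene on the minus strand of chromosome 8 from 84841850 to 84846934 (mm10). Fitted on the 6 libraries of day 7 alone, the day 7 change kept its size but not the call (adjusted p = 0.0732, over the alternatives 3.6e-06 to 0.0732).

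All 5 factors were called higher in each infected group than at day 0, and none was called between shCalr and shNT in the main fit. Without the 5 libraries farthest in GC slope, Gata4 (-0.60, adjusted p = 0.00648) and Sall4 (-0.39, 0.0431) were called lower with shCalr at day 7. Mef2c was at 0.34 there and not called (0.371). Gata4 had 17.6 ± 5.98 FPKM at day 0, 208 ± 103 and 216 ± 69.7 in shNT and shCalr at day 7, and 265 ± 18.5 and 169.5 ± 14.2 at day 14. Mef2c had 2.61 ± 1.19 at day 0, 26.1 ± 8.95 and 25.9 ± 15 at day 7, and 7.89 ± 0.827 and 18.3 ± 9.94 at day 14. Tbx5 and Myocd were at 0.334 ± 0.184 and 0.0207 ± 0.0249 at day 0 and at 40.8 ± 22.1 and 25.8 ± 9.16 in shCalr day 7, against 49.5 ± 29 and 27 ± 9.51 in shNT day 7. At day 14 Tbx5 stood at 24.4 ± 11.6 in shCalr and 20.9 ± 2.23 in shNT, and Myocd at 14.4 ± 3.32 and 16.4 ± 1.18. Sall4, listed at 0 in day 0, reached 47 ± 23.2 in shNT and 45.6 ± 1.05 in shCalr at day 7, and 37.2 ± 0.954 and 34.3 ± 0.685 at day 14. As a list the factors had a median change of -0.06 between shCalr and shNT at day 7 (camera adjusted p = 0.794) and -0.11 at day 14, where the mean was 0.04 (adjusted p = 0.88). In limma 0 of 5 were called at either day, adjusted over the list alone as well, with 0 at an unadjusted p under 0.05. Against day 0 the list was higher in shNT day 7 (adjusted p = 3.3e-07), with 5 of 5 called, and adjusted over the list alone too. It was also higher in shNT day 14 (0.000102, but adjusted p = 0.0645 with an estimated correlation, 2.3e-07 to 0.0645 over its alternatives), again with 5 of 5 called both ways. RNA from the vectors and from the cells' own copies could not be told from each other in these values. Mef2c at day 14 lost its call in shNT without any one of the 6 libraries. Its adjusted p was 0.0526, 0.113 and 0.0667 without day 0 replicates 1, 2 and 3 and 0.0724, 0.0891 and 0.0939 without shNT day 14 replicates 1, 2 and 3 (0.00637 to 0.113 over its alternatives).

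The comparison of shNT with day 0 asks what the factors and the days in culture did together in cells with the non-targeting hairpin, since no uninfected cells were sampled later. By day 7 genes of the cardiac contractile apparatus went from near 0 to high levels. Myl7, the atrial light chain, and Actc1, cardiac alpha-actin, were listed at 0 in day 0 and had 424 ± 188 and 306 ± 49.6 FPKM. Csrp3 and Myh6, an alpha-myosin heavy chain, were also listed at 0 and had 97.2 ± 32.3 and 80.6 ± 37.7. Cardiac troponins T and C, Tnnt2 and Tnnc1, rose by 8.38 and 8.24 log2 to 382 and 476, and Myl4 and Acta1 by 8.19 and 7.96. Outside the contractile genes, Krt18 of the epicardial list and Fabp3 (a fatty acid carrier of muscle) rose by 6.41 and 6.01. Of the sarcomere list, 25 of 29 members were called higher, 0 lower and 4 neither, with 25 and 0 adjusted over the list alone, camera adjusted p = 7.5e-28. Calcium handling and excitation genes were higher (12 of 19 members higher and 0 lower, 13 and 1 adjusted over the list alone, median 1.52, adjusted p = 2.3e-09). Smooth muscle genes such as Myh11 (5.51) were higher, with 11 of 12 members higher and 0 lower, 11 and 0 adjusted over the list alone (adjusted p = 1.0e-12). Skeletal muscle genes had 9 of 10 members higher and 0 lower, 9 and 0 adjusted over the list alone (adjusted p = 1.8e-09). Genes of fatty acid oxidation and mitochondria such as Ldhb (2.80) were higher (11 of 21 members higher and 0 lower, 13 and 0 adjusted over the list alone, median 0.79, adjusted p = 1.0e-06). In the p53 and senescence list Perp was at 5.33 and the cell cycle inhibitors Cdkn2a and Cdkn1a at 1.99 and 1.05. The list was higher (6 of 18 members higher and 0 lower, 7 and 0 adjusted over the list alone, median 0.74, adjusted p = 0.00115).

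Fibroblast, interferon and macrophage genes fell over the same 7 days. At day 0 macrophage markers were about as high as fibroblast genes. Mean log2(FPKM + 1) per library was 6.00 to 6.17 for the macrophage list and 6.07 to 6.14 for the fibroblast list. Falls from day 0, at either day, therefore cannot be told apart from a changed share of cell types in these bulk values. The largest falls were in Mmp3, a matrix protease (-4.81, 7.78 ± 2.6 against 239.9 ± 25.7 FPKM), the chemokine Ccl8 (-4.74), Kcne4 (-4.50), the Wnt antagonist Sfrp1 (-4.46), Plac8 (-4.14), Olfr1033 (-4.07), the microfibril gene Mfap4 (-4.07), Fcrls (-3.83) and the interferon-induced Ifit3 and Ifit1 (-3.81 and -3.80). The fibroblast list had 2 of 30 members higher and 19 lower, 3 and 20 adjusted over the list alone, a median of -1.77 and an adjusted p of 8.0e-10. Its growth factor receptors Pdgfra and Pdgfrb were at -2.14 and -2.71. Interferon genes had 0 of 20 members higher and 17 lower, 0 and 18 adjusted over the list alone (median -1.92, adjusted p = 1.3e-15). Inflammation genes, the complement gene C3 among them (-2.68), had 0 of 17 members higher and 8 lower, 0 and 8 adjusted over the list alone (median -0.50, adjusted p = 0.000296). Macrophage markers were lower (1 of 20 members higher and 15 lower, 1 and 16 adjusted over the list alone, median -1.51, adjusted p = 1.1e-09), with lysozyme Lyz2 at 1919 ± 256 against 6045 ± 902 FPKM. Epicardial markers were higher (5 of 11 members higher and 2 lower, 7 and 2 adjusted over the list alone, adjusted p = 0.0139), Msln by 4.95. Without the 5 libraries farthest in GC slope the epicardial and inflammation calls ended (0.212, 5.2e-09 to 0.212 over its alternatives, and 0.0501, 1.1e-06 to 0.0501). Endothelial markers were not called as a list (3 of 12 members higher and 1 lower, 3 and 1 adjusted over the list alone, adjusted p = 0.2). Nor were pericyte markers (2 of 5 members higher and 1 lower, 2 and 1 adjusted over the list alone, adjusted p = 0.0614).

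Stress response genes including the serine synthesis enzyme Psat1 (2.49) were higher at day 7 in the integrated stress list (8 of 22 members higher and 0 lower, 10 and 0 adjusted over the list alone, median 0.76, adjusted p = 0.00018, but adjusted p = 0.11 with an estimated correlation, 1.7e-05 to 0.11 over its alternatives). The remaining lists were not called. TGF-beta and myofibroblast genes went both ways (8 of 25 members higher and 11 lower, 9 and 12 adjusted over the list alone, median -0.38, mean 0.06, adjusted p = 0.286). Cardiac regulators had 7 of 12 members higher and 2 lower, 7 and 3 adjusted over the list alone (adjusted p = 0.0819). Chaperones had 0 of 24 members higher and 1 lower, 0 and 1 adjusted over the list alone (0.39). Cell cycle genes had 5 of 31 members higher and 1 lower, 5 and 1 adjusted over the list alone (0.487). Glycolysis genes had 1 of 15 members higher and 3 lower, 1 and 3 adjusted over the list alone (0.2). Store-operated calcium genes had 2 of 17 members higher and 2 lower, 2 and 2 adjusted over the list alone (0.993), with a median of -0.08 and a mean of 0.09. Mitochondrially encoded mRNA had a median of -1.20 with 0 of 13 members called in limma, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05 (0.163). Of 4 cartilage and bone genes 2 were lower, Spp1 among them (-3.17), and of 3 adipocyte genes 1 was higher. In all 3214 genes were called, 1755 higher and 1459 lower. Without shNT day 7 replicate 3, whose mitochondrial share and GC slope were near those of day 0 replicates 1 and 3, 6213 were called. With the 6 libraries alone the count was 1375, and without the 5 libraries farthest in GC slope 9000. With quantile normalization 1494 were higher and 1512 lower.

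By day 14 with shNT contractile genes were again among the largest rises, and Krt18 of the epicardial list was too. Actc1, Myl7, Myh6 and Csrp3 had 809 ± 43.6, 337 ± 30.4, 241 ± 20.4 and 195 ± 10.6 FPKM, all listed at 0 in day 0. Tnnc1 rose by 8.86, Tnnt2 by 8.73, Myl4 by 8.46, Acta1 by 7.82, Krt18 by 7.34 and the myosin-binding Mybpc3 by 7.17. The sarcomere list had 27 of 29 members higher and 0 lower, 27 and 0 adjusted over the list alone (adjusted p = 1.6e-23). Calcium handling genes had 13 of 19 members higher and 1 lower, 14 and 1 adjusted over the list alone (median 2.06, 1.8e-08). Smooth muscle genes had 11 of 12 members higher and 0 lower, 11 and 0 adjusted over the list alone (1.2e-09). Skeletal muscle genes had 9 of 10 members higher and 0 lower, 10 and 0 adjusted over the list alone (1.8e-08). Fatty acid and mitochondrial genes had 14 of 21 members higher and 0 lower, 15 and 0 adjusted over the list alone (4.9e-05). The p53 and senescence list had 11 of 18 members higher and 0 lower, 11 and 0 adjusted over the list alone (0.000261), with Cdkn2a at 65 ± 8.52 against 3.97 ± 2.61 FPKM. Epicardial markers had 7 of 11 members higher and 2 lower, 7 and 2 adjusted over the list alone (0.00206), Msln reaching 140.0 ± 3.19. The integrated stress list had 11 of 22 members higher and 1 lower, 13 and 1 adjusted over the list alone (0.000659, but adjusted p = 0.138 with an estimated correlation, 2.5e-05 to 0.138 over its alternatives).

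Falls at day 14 included the matrix genes Mfap4 (-4.57) and Postn (-3.38), the chemokine Ccl8 (-4.39), Ms4a6d (-4.44) and Ifit1 (-4.48). The fibroblast list had 3 of 30 members higher and 18 lower, 3 and 18 adjusted over the list alone (adjusted p = 5.3e-07). Interferon genes had 0 of 20 members higher and 19 lower, 0 and 20 adjusted over the list alone (2.5e-13). Macrophage markers had 1 of 20 members higher and 18 lower, 1 and 19 adjusted over the list alone (2.3e-09), with Lyz2 at 1219.7 ± 80.9 FPKM. Inflammation genes had 2 of 17 members higher and 9 lower, 2 and 9 adjusted over the list alone (0.0039, but adjusted p = 0.0889 with an estimated correlation, 1.8e-06 to 0.0889 over its alternatives). Endothelial markers were not called as a list (3 of 12 members higher and 6 lower, 3 and 6 adjusted over the list alone, 0.203), with Cdh5 at -1.75 and Pecam1 at -1.19. The other largest falls were in mitochondrial transcripts, beside the lower mitochondrial share. They were mt-Nd4 (-5.38, 41.9 ± 8.58 against 2113 ± 1299 FPKM), mt-Nd2 (-4.53), mt-Tp (-5.41), mt-Tn (-4.42) and mt-Atp6 (-5.84, adjusted p = 0.0308), with mt-Te listed at 0 against 32.6 ± 19.4 at day 0. The mitochondrially encoded list had 0 of 13 members higher and 10 lower, 0 and 10 adjusted over the list alone, a median of -3.71 and an adjusted p of 0.00148. It had adjusted p = 0.391 with an estimated correlation, 3.1e-06 to 0.391 over its alternatives. The call of mt-Nd4 ended without day 0 replicate 1 (adjusted p = 0.0535) and that of mt-Tp without day 0 replicate 1 or 3 (0.0526 and 0.0520). For mt-Atp6, mt-Nd2 and mt-Te it ended without day 0 replicate 1 or 3 or any shNT day 14 library (0.0558 to 0.129), and for mt-Tn without these except shNT replicate 2 (0.0831 to 0.103). Over all their alternatives the 6 ranged from 1.6e-06 to 0.176.

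Among lists not called at day 14, cardiac regulators had 7 of 12 members higher and 3 lower, 7 and 3 adjusted over the list alone (adjusted p = 0.0811). Chaperones had 2 of 24 members higher and 2 lower, 1 and 1 adjusted over the list alone (0.467), and glycolysis 3 of 15 members higher and 3 lower, 3 and 3 adjusted over the list alone (0.483). Pericyte markers had 3 of 5 members higher and 1 lower, 3 and 1 adjusted over the list alone (0.121). TGF-beta and myofibroblast genes had 8 of 25 members higher and 13 lower, 8 and 13 adjusted over the list alone, a median of -1.07 and a mean of 0.01 (0.203). Store-operated calcium genes had 4 of 17 members higher and 3 lower, 4 and 3 adjusted over the list alone, with a median of -0.09 and a mean of 0.19 (0.806). Cell cycle genes had 4 of 31 members higher and 4 lower, 4 and 3 adjusted over the list alone, with a median of -0.14 and a mean of 0.00 (0.467). Of 4 cartilage and bone genes 3 were lower and of 3 adipocyte genes 2 were higher. In all 5745 genes were called, 3159 higher and 2586 lower, and 8872 without the 5 libraries farthest in GC slope. With quantile normalization 2648 were higher and 2975 lower.

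The comparison of shCalr with shNT asks what knockdown of Calr RNA changes in cells given the same factors. At day 7 the largest rise was in Scg2, a secretory granule protein (3.25 log2, 32.5 ± 1.34 against 2.57 ± 0.612 FPKM, adjusted p = 3.9e-08; ENSMUSG00000050711, chromosome 1 from 79434669 to 79440120). Contractile genes rose too. Actc1 rose by 2.18 (1379 ± 49.3 against 306 ± 49.6, adjusted p = 1.9e-06; ENSMUSG00000068614, chromosome 2 from 114047282 to 114053548). The Z-disc protein gene Actn2 rose by 2.51 (10.6 ± 2.56 against 1.09 ± 0.695), Myh6 by 2.19 (340.3 ± 62.7 against 80.6 ± 37.7) and Myom1 by 1.24. Of the sarcomere list, 8 of 29 members were called higher, 1 lower and 20 neither, with 17 and 3 adjusted over the list alone. Its median was 0.47 (camera adjusted p = 1.2e-08, but 0.0418 with an estimated correlation). Mybpc3, chosen after its values were seen as the member called lower, fell by 0.89 (25.4 ± 6.18 against 48.1 ± 11.1). Calcium handling and excitation genes were higher (6 of 19 members higher and 0 lower, 8 and 0 adjusted over the list alone, median 0.43, adjusted p = 1.9e-08). Examples are the potassium channel Kcnj5 (1.57), the sodium-calcium exchanger Slc8a1 (1.22) and the pacemaker channel Hcn4 (1.42, 28.3 ± 5.02 against 10.2 ± 3.43). Cardiac regulators had 3 of 12 members higher and 0 lower, 6 and 0 adjusted over the list alone (median 0.58, adjusted p = 0.000263).

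Other muscle genes were higher with shCalr at day 7. Skeletal muscle genes had 7 of 10 members higher and 0 lower, 8 and 0 adjusted over the list alone (median 1.09, adjusted p = 2.3e-11, but 0.0115 with an estimated correlation). Tnnt1 was at 2.22, Myh1 at 2.10 (20.3 ± 1.34 against 4.1 ± 1.35), Myh2 at 1.98 and Myh4 at 1.20. Smooth muscle genes had 5 of 12 members higher and 0 lower, 10 and 0 adjusted over the list alone (median 0.93, adjusted p = 4.3e-09). Myh11 was at 1.76, Des at 1.38, Actg2 at 1.25 and Acta2 at 1.03 (3303 ± 479 against 1662 ± 539.5). Pericyte markers had 2 of 5 members higher and 0 lower, 4 and 0 adjusted over the list alone (adjusted p = 1.0e-05; Rgs5 1.28, Mcam 1.24). Endothelial markers had 1 of 12 members higher and 0 lower, 8 and 0 adjusted over the list alone (2.1e-05; Esam 1.18). Epicardial markers had 3 of 11 members higher and 0 lower, 6 and 2 adjusted over the list alone (0.0346; Wt1 0.94, Aldh1a2 0.90). The epicardial call did not hold everywhere (adjusted p = 0.0758 with an estimated correlation, 0.000527 to 0.143 over its alternatives, and 0.0696, 0.143 and 0.0591 without shCalr day 7 replicate 2, shNT day 7 replicate 2 and shNT day 7 replicate 3). Macrophage markers had a median of 0.33 with 0 of 20 members higher and 0 lower, 6 and 0 adjusted over the list alone and 10 at an unadjusted p under 0.05 in limma. The list test gave an adjusted p of 0.00125, but adjusted p = 0.0732 with an estimated correlation, 0.000228 to 0.0732 over its alternatives. Fibroblast and matrix genes were also higher (6 of 30 members higher and 0 lower, 10 and 0 adjusted over the list alone, median 0.33, adjusted p = 0.000169), among them the collagen gene Col6a3 (1.09, 22 ± 3.57 against 9.87 ± 2.43).

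Interferon-induced genes were higher with shCalr at day 7 (6 of 20 members higher and 0 lower, 8 and 0 adjusted over the list alone). Their median was 0.50 (adjusted p = 9.0e-06, but 0.0302 with an estimated correlation). Isg15 rose by 2.09 (25.9 ± 13.6 against 5.25 ± 2.89), Ifit1 by 1.87 and Ifit3 by 1.28. Inflammation genes had 2 of 17 members higher and 0 lower, 3 and 0 adjusted over the list alone (adjusted p = 0.0107, but adjusted p = 0.11 with an estimated correlation, 0.00121 to 0.11 over its alternatives), and 0.0618 without shNT day 7 replicate 2. Cell cycle genes were higher as a list (median 0.26, adjusted p = 0.00189) with 1 of 31 members higher and 0 lower, 1 and 0 adjusted over the list alone. Chaperones of the endoplasmic reticulum had a median of 0.24 and 0 of 24 members higher and 0 lower, 4 and 0 adjusted over the list alone, 7 at an unadjusted p under 0.05 in limma. The list test gave an adjusted p of 0.0107, but adjusted p = 0.282 with an estimated correlation, 0.000582 to 0.282 over its alternatives, and 0.0893 and 0.157 without replicate 1 of shCalr or of shNT day 7. The remaining lists were not called. TGF-beta and myofibroblast genes had 2 of 25 members higher and 1 lower, 6 and 4 adjusted over the list alone (adjusted p = 0.0587). Integrated stress genes had 0 of 22 members higher and 2 lower, 1 and 2 adjusted over the list alone (0.952). The p53 and senescence list had 1 of 18 members higher and 0 lower, 1 and 0 adjusted over the list alone (0.563). Fatty acid and mitochondrial genes had 1 of 21 members higher and 0 lower, 1 and 0 adjusted over the list alone (0.794). Glycolysis genes had 0 of 15 members higher and 0 lower, 2 and 0 adjusted over the list alone, and 5 at an unadjusted p under 0.05 (0.0696). Store-operated calcium genes had 1 of 17 members higher and 0 lower, 3 and 2 adjusted over the list alone, with a median of -0.05 and a mean of 0.01 (0.794). Mitochondrially encoded mRNA had 0 of 13 members higher and 0 lower, 0 and 0 adjusted over the list alone with 0 at an unadjusted p under 0.05 and a median of -0.82 (0.366). Among 4 cartilage and bone genes 1 was called higher, and 0 of 3 adipocyte genes were called, 0 at an unadjusted p under 0.05.

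Other large rises at day 7 were the imprinted gene Mest (2.59), the keratin Krt17 (2.56) and Mir351 (2.20, adjusted p = 0.041). The largest fall was in Slc6a18, a neutral amino acid transporter (-3.62, 0.703 ± 0.0512 against 20.3 ± 5.52 FPKM, adjusted p = 3.9e-08; ENSMUSG00000021612, chromosome 13 from 73661752 to 73678023). It was followed by the serpins Serpinb6c (-2.24), Serpinb9b (-2.11), Serpinb1a (-1.92) and the glutathione transferase Gsta1 (-2.10). Further falls were in the heat shock gene Hspa1b (-1.96, 6.46 ± 0.993 against 28.3 ± 6.8), Wfdc21 (-1.88), the synaptotagmin Syt13 (-1.88, 5.67 ± 0.568 against 23.6 ± 3.07) and the Wnt ligand Wnt7a (-1.82, 6.15 ± 0.367 against 24.7 ± 6.52). In all 678 genes were called, 463 higher and 215 lower. The calls numbered 412 and 370 without shCalr day 7 replicates 2 and 3 and 7 with the 6 libraries alone. They numbered 1329 (774 higher, 555 lower) after a GC correction and 2031 (1089 higher, 942 lower) without the 5 libraries farthest in GC slope. With 7 calls left in the fit on the 6 libraries alone, most genes named at day 7 lost their call there. Acta2 also lost its call without shCalr day 7 replicate 3 (adjusted p = 0.0554, 0.00183 to 0.423 over its alternatives), and Mir351 without shCalr replicates 1, 2 and 3 (0.0853, 0.118 and 0.109) or shNT replicates 2 and 3 (0.122 and 0.0976, 0.0142 to 0.135 over its alternatives).

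**Figure D2:**
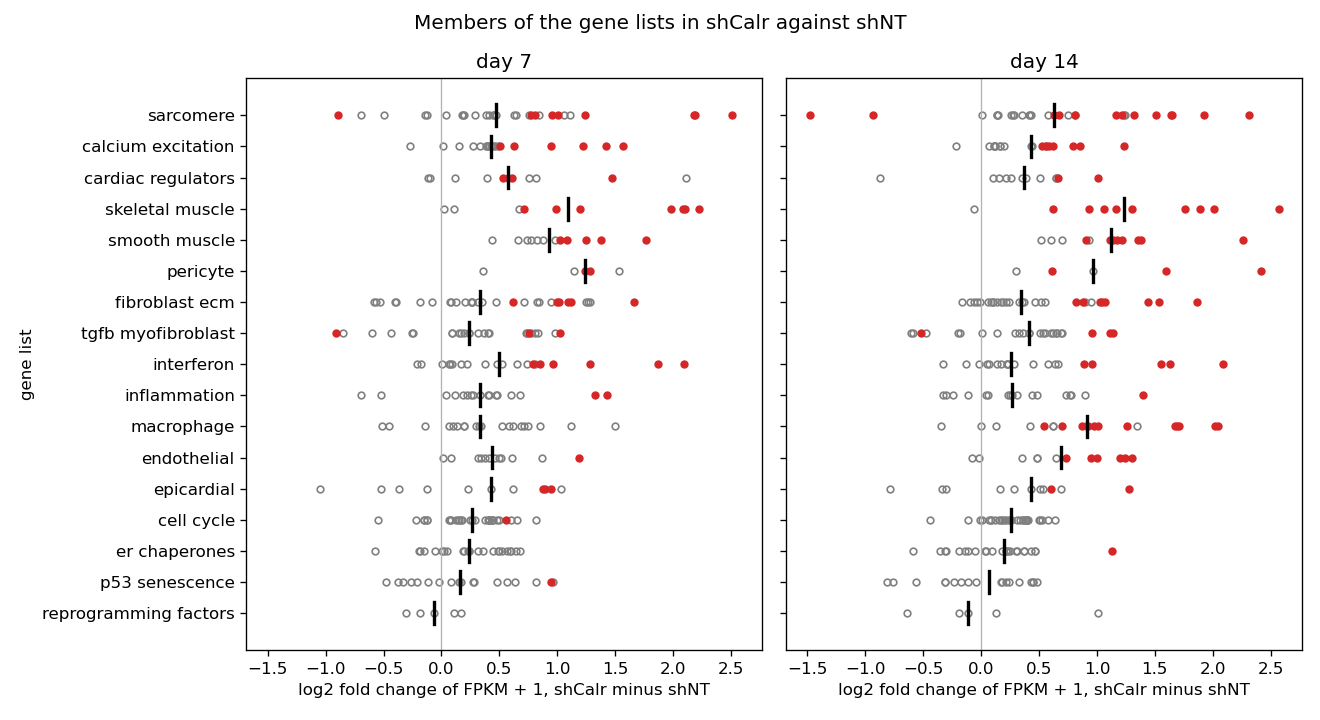
Log2 change, shCalr minus shNT, of each tested member of 17 fixed gene lists at day 7 and day 14, on one axis. Red points are called genes, open grey points are not, and the black bar is the list median, which is 0.47 and 0.63 for the sarcomere list and 0.33 and 0.91 for the macrophage list.

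At day 14 Scg2 was again the largest rise (3.80, 71.2 ± 1.94 against 4.2 ± 0.234 FPKM, adjusted p = 5.3e-09). The water channel Aqp1 rose by 3.08 (26.5 ± 1.65 against 2.27 ± 0.381), Mest by 2.60, Krt17 by 2.52, Nrgn by 2.39 and Ndufa4l2 by 2.42. Actn2 had 29.6 ± 3.23 against 5.13 ± 0.298 (2.31; ENSMUSG00000052374, chromosome 13 from 12269426 to 12340760). Actc1 had 2518 ± 100.3 against 809 ± 43.6 (1.64), and the beta-myosin gene Myh7 6.44 ± 1.28 against 0.943 ± 0.127 (1.92). Of the sarcomere list, 11 of 29 members were called higher, 2 lower and 16 neither, with 17 and 2 adjusted over the list alone. Its median was 0.63 (camera adjusted p = 5.5e-12, but 0.0183 with an estimated correlation). The members called lower, named after their values were seen, were Mybpc3 (-1.48, 54 ± 6.18 against 152 ± 10.2) and Csrp3 (-0.93). Calcium handling had 7 of 19 members higher and 0 lower, 8 and 0 adjusted over the list alone (median 0.43, adjusted p = 4.9e-06; Kcnj5 0.80, 36.7 ± 3.57 against 20.6 ± 1.21). Cardiac regulators had 2 of 12 members higher and 0 lower, 2 and 1 adjusted over the list alone (0.0177). The natriuretic peptide gene Nppb was at -0.87 and not called (adjusted p = 0.050). Skeletal muscle genes had 9 of 10 members higher and 0 lower, 9 and 0 adjusted over the list alone (2.8e-13; Tnnt3 2.57, 36.2 ± 6.36 against 5.22 ± 0.416). Smooth muscle genes had 8 of 12 members higher and 0 lower, 10 and 0 adjusted over the list alone (8.3e-11; Actg2 2.26, Mylk 1.38, Des 1.35).

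Macrophage markers were higher with shCalr at day 14 (12 of 20 members higher and 0 lower, 15 and 0 adjusted over the list alone, median 0.91, adjusted p = 3.7e-12). The complement gene C1qb had 354 ± 74 against 107 ± 18.2 FPKM (1.70). Aif1 rose by 1.67, the mannose receptor Mrc1 by 2.04, and Fcrls and F13a1, which resident macrophages express, by 2.40 and 2.34. Lyz2 was at 2304 ± 18.1 against 1219.7 ± 80.9 (0.92), but its call ended with quantile normalization and without the filter (adjusted p = 0.411 and 0.336, 0.00152 to 0.411 over its alternatives). Day 0 was above both, with a C1qb FPKM of 619 ± 90.4. Endothelial markers had 6 of 12 members higher and 0 lower, 10 and 0 adjusted over the list alone (4.5e-08; Pecam1 1.87 ± 0.175 against 0.497 ± 0.192, Cdh5 2.78 ± 0.366 against 0.642 ± 0.116, Sox18 1.30). Pericyte markers had 3 of 5 members higher and 0 lower, 4 and 0 adjusted over the list alone (2.7e-05; Mcam 1.59). Epicardial markers had 2 of 11 members higher and 0 lower, 4 and 1 adjusted over the list alone (0.0168; Aldh1a2 1.27). Without the 5 libraries farthest in GC slope the epicardial call ended (0.0846, 0.000277 to 0.0846 over its alternatives). Of 3 adipocyte genes 1 was called lower and of 4 cartilage and bone genes 1 higher. Fibroblast and matrix genes were higher (8 of 30 members higher and 0 lower, 9 and 0 adjusted over the list alone, median 0.34, 9.5e-06), with periostin, Postn, at 13.6 ± 1.53 against 2.99 ± 0.142 (1.87) and Mgp at 256 ± 13.2 against 93.5 ± 7.76. TGF-beta and myofibroblast genes had 3 of 25 members higher and 1 lower, 5 and 2 adjusted over the list alone (median 0.42, adjusted p = 0.00648), with Thbs1 at 0.96 and Cnn1 at 1.11.

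Interferon genes had 5 of 20 members higher and 0 lower, 7 and 0 adjusted over the list alone at day 14 (median 0.26, adjusted p = 0.000177; Ifit1 1.56). Inflammation genes had 1 of 17 members higher and 0 lower, 2 and 0 adjusted over the list alone (0.0135, but adjusted p = 0.117 with an estimated correlation, 0.00317 to 0.117 over its alternatives). Cell cycle genes were higher as a list (median 0.26, 0.00127) with 0 of 31 members higher and 0 lower, 0 and 0 adjusted over the list alone and 9 at an unadjusted p under 0.05 in limma. Glycolysis had 2 of 15 members higher and 0 lower, 2 and 0 adjusted over the list alone (0.0267, but adjusted p = 0.509 with an estimated correlation, 0.0218 to 0.509 over its alternatives, and 0.0524 without shCalr day 14 replicate 2). Mitochondrially encoded mRNA had a median of 1.58 with 0 of 13 members higher and 0 lower, 0 and 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (0.0267). It had adjusted p = 0.555 with an estimated correlation, 0.00173 to 0.555 over its alternatives, and 0.334 and 0.0534 without replicate 1 of shCalr or of shNT day 14. This stood beside mitochondrial shares of 1.14 ± 1.17% in shCalr and 0.252 ± 0.0494% in shNT. Chaperones were not called as a list (1 of 24 members higher and 0 lower, 1 and 0 adjusted over the list alone, 0.185). The translocon subunit Sec61b was the member called, named after its values were seen (1.13). Fatty acid and mitochondrial genes had 1 of 21 members higher and 1 lower, 1 and 1 adjusted over the list alone (0.202). In integrated stress 0 of 22 genes were called in limma and 4 had an unadjusted p under 0.05 (0 and 0 adjusted over the list alone, 0.199). In store-operated calcium it was 0 of 17 and 4 (0 and 0 adjusted over the list alone, 0.996). In p53 and senescence it was 0 of 18 and 4 (0 and 0 adjusted over the list alone, 0.88), where the median was 0.07, the mean -0.02 and the test's direction down.

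Slc6a18 had the largest fall at day 14 (-4.16, 0.775 ± 0.0945 against 30.7 ± 0.869 FPKM, adjusted p = 5.3e-09). It was followed by Gsta1 (-2.69), Syt13 (-2.62, 6.32 ± 0.639 against 43.9 ± 2.57), the thyroid hormone deiodinase Dio3 (-2.19) and Serpinb6c (-2.13). Smaller falls were in Pcolce2 (-2.10), Slc22a18 (-1.96), Ptprn (-1.93), Wnt7a (-1.89, 12.2 ± 0.852 against 48.2 ± 3.41) and Crct1 (-1.85). In all 914 genes were called, 580 higher and 334 lower. Ndufa4l2 lost its call without shCalr replicates 1 and 3 (adjusted p = 0.0619 and 0.0642) or shNT replicates 1, 2 and 3 (0.0555, 0.0668 and 0.0549, 0.000209 to 0.0668 over its alternatives), and Serpinb6c with a pseudocount of 0.1 (0.0821, 0.000531 to 0.0821). Removing any one of the 6 libraries left 475 to 561 calls (523, 561 and 475 without shCalr replicates 1, 2 and 3, and 493, 494 and 486 without those of shNT). With the 6 libraries alone 3353 genes were called (1672 higher, 1681 lower), after a GC correction 1738, and without the 5 libraries farthest in GC slope 1769.

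**Figure D3:**
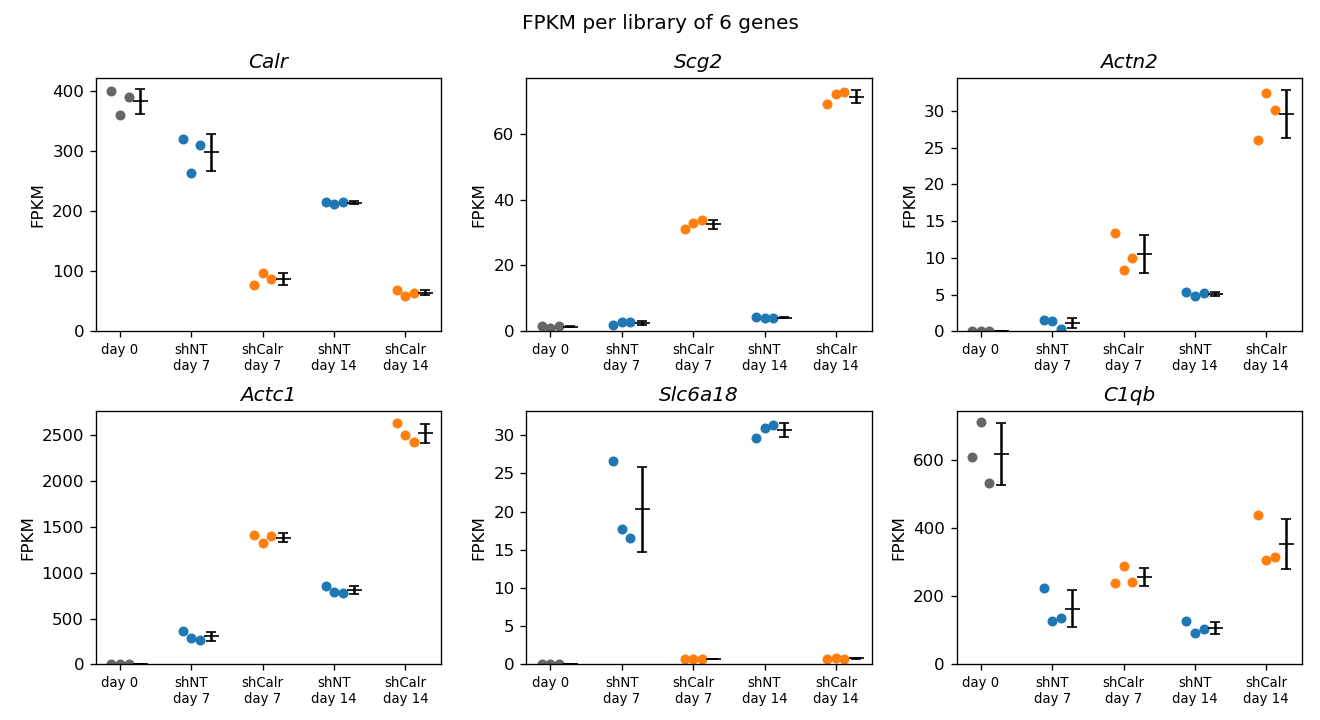
FPKM per library (linear axis from 0) of Calr, Scg2, Actn2, Actc1, Slc6a18 and C1qb in the 5 groups. Points are libraries and black bars the mean ± SD of 3, and at day 14 Scg2 was at 71.2 ± 1.94 in shCalr against 4.2 ± 0.234 in shNT and Slc6a18 at 0.775 ± 0.0945 against 30.7 ± 0.869.

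The day 7 and day 14 effects of shCalr compare different libraries, but both tests use the same spread per gene, from all 15 libraries. Genes called at both days in the same direction numbered 432, 302 higher and 130 lower, and 0 were called in opposite directions. Independent calls would give 24.6. That number is too low a bar, since a gene with a low spread is easier to call at both days. Fitted on the libraries of its contrast alone, day 7 had 7 calls, so few could overlap. Among the 678 genes called at day 7, 97.3% had the same sign at day 14. Across all tested genes, which are not independent replicates, the changes correlated with a Pearson r of 0.501 and a Spearman rho of 0.443. The test of the difference between the days called Hspa1b alone (2.32, adjusted p = 0.0285). This call ended with the replicate block, a GC correction, voom, the libraries of the contrast alone and without the 5 libraries farthest in GC slope. Over the alternatives with all libraries or those 5 left out, its adjusted p in limma ran from 0.0154 to 0.255. Hspa1b was at 28.3 ± 6.80 FPKM in shNT day 7, 6.46 ± 0.993 in shCalr day 7, 3.69 ± 0.623 in shNT day 14 and 5.08 ± 1.13 in shCalr day 14. With it 538 genes had an unadjusted p under 0.05 in limma. Of the lists, macrophage markers were called for the difference (median 0.54, 0 of 20 members called in limma, 0 adjusted over the list alone and 7 at an unadjusted p under 0.05, camera adjusted p = 3.2e-08, but 0.0382 with an estimated correlation). So was mitochondrially encoded mRNA (median 2.26, 0 of 13 members called, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, adjusted p = 0.00239, but adjusted p = 0.73 with an estimated correlation, 0.000104 to 0.794 over its alternatives). Sarcomere (0.401), endothelial (0.0767) and the other lists were not, though the endothelial list was after a GC correction (camera adjusted p = 0.0386). With a library left out, 2 to 6 lists were called. Removing a library left 0 calls in limma in 10 of 12 fits, with 330 to 810 genes at an unadjusted p under 0.05, including every removal from day 14. There were 3 calls without shCalr day 7 replicate 1 and 1 without shNT day 7 replicate 3, and the overlap ranged from 252 to 559 genes.

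The next test asked whether shCalr moved the genes that the factors and the days in culture move together. The genes were the 200 largest rises and 200 largest falls of shNT against day 0. Those of each day were tested in the shCalr effect of the other day. Genes that rose by day 14 were higher with shCalr at day 7 (median 0.41, 44 called higher and 14 lower, adjusted p = 2.7e-08, but adjusted p = 0.274 with an estimated correlation). Genes that fell by day 14 had a median of 0.09, 20 called higher and 2 lower (adjusted p = 0.0419, but adjusted p = 0.611 with an estimated correlation and 0.356 with fry, from 7.1e-07 to 0.886 over the fits without a library). Genes that rose by day 7 had a median of 0.14 in the day 14 effect, 36 called higher and 30 lower, and were not called (adjusted p = 0.157). Genes that fell by day 7 were higher with shCalr at day 14 (median 0.43, 45 called higher and 3 lower, adjusted p = 7.4e-16, and 0.0204 with an estimated correlation).

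Against day 0, shCalr cells at day 7 had Actc1 at 1379 ± 49.3 FPKM (listed at 0 in day 0), Tnnc1 at 9.30 log2 and Myl4 at 8.84, and falls in Mmp3 (-4.59), Clca3a1 (-4.42) and Ccl8 (-4.39). At day 14 Actc1 was at 2518 ± 100.3 and Myl7 at 808 ± 204 (both listed at 0 in day 0), Tnnc1 at 9.28, Ccl8 at -4.79, Clca3a1 at -4.28 and Mfap4 at -4.24. The sarcomere list had 27 of 29 members higher and 0 lower, 28 and 0 adjusted over the list alone at day 7 and 29 of 29 members higher and 0 lower, 29 and 0 adjusted over the list alone at day 14. Macrophage markers were lower, with 1 of 20 members higher and 12 lower, 2 and 12 adjusted over the list alone at day 7 (adjusted p = 2.7e-05). At day 14 they had 2 of 20 members higher and 11 lower, 2 and 11 adjusted over the list alone (0.00325, but adjusted p = 0.0914 with an estimated correlation). Calls numbered 4654 at day 7 (2549 higher, 2105 lower) and 5224 at day 14 (2869 higher, 2355 lower), and with quantile normalization 2102 were higher and 2549 lower at day 7 and 2425 higher and 3006 lower at day 14. Without day 0 replicates 1 and 3 the day 7 calls were 3028 and 3058, and without the 5 libraries farthest in GC slope 7935 at day 7 and 8789 at day 14.

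Between day 7 and day 14 with shNT, the carbonic anhydrase Car4 (2.26), the peptide hormone gene Cck (2.19) and Nppb (2.17, 131 ± 18.2 against 28.2 ± 3.04 FPKM) rose most, and Hspa1b (-2.63), Ifi27l2a (-2.11) and Angpt2 (-1.81) fell most. With shCalr, Car4 rose by 2.39 (30.7 ± 4.35 against 5.14 ± 1.47), Fcrl1 by 2.11 and Nkain4 by 1.91, and Col10a1 (-1.03), Itga10 (-0.77) and Zswim7 (-0.71) fell. Calcium handling genes were higher as a list in both, with 3 of 19 members higher and 0 lower, 6 and 0 adjusted over the list alone in shNT (adjusted p = 0.000106). In shCalr they had 0 of 19 members higher and 0 lower, 6 and 1 adjusted over the list alone (3.4e-05), with 9 at an unadjusted p under 0.05. Endothelial markers were lower as a list, with 1 of 12 members higher and 5 lower, 1 and 7 adjusted over the list alone in shNT (3.8e-06). In shCalr they had 0 of 12 members higher and 0 lower, 1 and 5 adjusted over the list alone (1.1e-06), with 7 at an unadjusted p under 0.05. Sarcomere genes had 7 of 29 members higher and 0 lower, 12 and 1 adjusted over the list alone with shNT (2.7e-06, but adjusted p = 0.15 with an estimated correlation). With shCalr they had 7 of 29 members higher and 0 lower, 16 and 0 adjusted over the list alone (5.4e-23, but 0.00447 with an estimated correlation).

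In all, 9 lists were called between the days with shNT and 13 with shCalr. Macrophage markers were lower with shNT (median -0.25, 0 of 20 members higher and 1 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.00843, but adjusted p = 0.171 with an estimated correlation). With shCalr they were higher (median 0.21, 0 of 20 members higher and 0 lower, 0 and 0 adjusted over the list alone, 3 at an unadjusted p under 0.05 in limma, adjusted p = 0.000189, but adjusted p = 0.0511 with an estimated correlation). Epicardial markers were higher with both, with 3 of 11 members higher and 0 lower, 5 and 0 adjusted over the list alone in shNT (0.000106) and 1 of 11 members higher and 0 lower, 7 and 0 adjusted over the list alone in shCalr (3.5e-10). Cell cycle genes were lower with both, with medians of -0.21 (0.00606) and -0.13 (3.2e-05). In limma 0 of 31 were called in either, 0 adjusted over the list alone, with 7 and 2 at an unadjusted p under 0.05. Skeletal muscle genes were higher, with 0 of 10 members higher and 0 lower, 5 and 0 adjusted over the list alone and 5 at an unadjusted p under 0.05 in shNT (0.0189, but adjusted p = 0.411 with an estimated correlation). In shCalr they had 1 of 10 members higher and 0 lower, 5 and 0 adjusted over the list alone (1.1e-06, but adjusted p = 0.0511 with an estimated correlation). Mitochondrially encoded mRNA was lower with shNT (median -2.56, 0 of 13 members higher and 0 lower, 0 and 0 adjusted over the list alone, 6 at an unadjusted p under 0.05, 0.000106, but adjusted p = 0.432 with an estimated correlation). Interferon genes were lower with shCalr (0 of 20 members higher and 0 lower, 0 and 3 adjusted over the list alone, 5 at an unadjusted p under 0.05, 0.000279, but adjusted p = 0.0778 with an estimated correlation). The p53 and senescence list was higher with shNT (2 of 18 members higher and 0 lower, 2 and 0 adjusted over the list alone, 0.0356, but adjusted p = 0.151 with an estimated correlation). With shCalr the list test was also called (0 of 18 members higher and 0 lower, 0 and 0 adjusted over the list alone, 2 at an unadjusted p under 0.05 in limma, 0.0434, but adjusted p = 0.143 with an estimated correlation). The list of the 5 factors was called lower with shCalr (0 of 5 members higher and 0 lower, 0 and 0 adjusted over the list alone, 1 at an unadjusted p under 0.05 in limma, 0.00656, but adjusted p = 0.162 with an estimated correlation). The list of integrated stress genes was called higher with shCalr (0 of 22 members higher and 0 lower, 0 and 0 adjusted over the list alone, 1 at an unadjusted p under 0.05 in limma, 0.00665, but adjusted p = 0.225 with an estimated correlation). So were the lists of fatty acid and mitochondrial genes (0 of 21 members higher and 0 lower, 0 and 0 adjusted over the list alone, 2 at an unadjusted p under 0.05 in limma, 0.00314, but adjusted p = 0.0511 with an estimated correlation) and of smooth muscle genes (0 of 12 members higher and 0 lower, 0 and 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 in limma, 0.0198, but adjusted p = 0.143 with an estimated correlation).

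Cck lost its call without shNT day 7 replicates 2 and 3 (0.0666 and 0.0573) or day 14 replicates 1 and 2 (0.0627 and 0.0986, 0.00804 to 0.129 over its alternatives). Ifi27l2a lost it without shNT day 7 replicates 1 and 3 (0.120 and 0.0936) or day 14 replicates 2 and 3 (0.160 and 0.181, 0.014 to 0.2). With shCalr, Car4 lost it with a pseudocount of 0.1 (0.271, 0.000168 to 0.271) and Col10a1 without day 14 replicate 3 (0.0673, 0.00441 to 0.271). Itga10 lost it without any library but day 14 replicate 2 (0.0717 to 0.150, 0.0113 to 0.348 over all alternatives) and Zswim7 without any but day 7 replicate 1 (0.0993 to 0.160, 0.0138 to 0.167). With shNT 302 genes were called, 248 higher and 54 lower, and 127, 120 and 139 without shNT day 14 replicates 1, 2 and 3. Its 6 libraries alone gave 0 calls in limma, with 1838 genes at an unadjusted p under 0.05, a GC correction gave 558, and the fit without the 5 libraries 1419 (890 higher, 529 lower). With shCalr 91 were called, 85 higher and 6 lower, 22 with TPM, 35 with a pseudocount of 0.1, 140 without the filter, 33 with its 6 libraries alone, 152 after a GC correction and 1201 (788 higher, 413 lower) without the 5 libraries. Without shCalr day 7 replicates 2 and 3 they numbered 32 and 38, and without shCalr day 14 replicates 1, 2 and 3, 43, 30 and 25.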

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

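The tests of a swap of libraries and of factor RNA against sarcomere genes, and the 82 splits and the subtracted effect in the last paragraph, were chosen only after the results were seen, as were both alternatives by GC, the bounds of 0.2 for the swap and the reading of the macrophage test. Between the days, the shCalr effect differed for Hspa1b by 2.32 log2 (adjusted p = 0.0285), for the macrophage list by a median of 0.54 (3.2e-08) and for mitochondrially encoded mRNA by a median of 2.26 (0.00239). For the macrophage list 0 of 20 members were called in limma. Its adjusted p was 0.0382 with an estimated correlation and 0.0222 with fry. For Hspa1b the difference lies in the high level of shNT day 7 (28.3 ± 6.80 FPKM against 3.69 to 6.46 in the other 3 infected groups), and reads shared with the near-identical Hspa1a were not examined. The mitochondrial difference rests on single libraries, with adjusted p = 0.279, 0.054 and 0.197 without shCalr day 7 replicate 1, shCalr day 14 replicate 1 and shNT day 7 replicate 3, and it turned negative without the 5 libraries farthest in GC slope (0.000536, 0.000104 to 0.794 over its alternatives).

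The first pattern is the spread of mitochondrial share and GC slope between libraries of one group. A GC bias as the whole source of the mitochondrial spread is argued against. The within-group SD after a GC correction was 0.843 of that before (1.36 against 1.61 log2). GC bias as the source of the shCalr calls is argued against too. A share of 0.916 of those at day 7 and 0.942 of those at day 14 stayed called in the same direction. At day 14 the mean GC slopes were close, 0.149 ± 0.0412 in shCalr and 0.160 ± 0.0436 in shNT. The correction could therefore end few calls there, and the day 14 share decides little. The correction also raised the calls from 678 to 1329 and from 914 to 1738, which makes staying called easier. Of the 10 splits of the shNT day 7 and day 0 libraries, 2 called at least as many genes as the real 3214, and the split that sets shNT day 7 replicates 1 and 2 with day 0 replicate 2 against shNT day 7 replicate 3 with day 0 replicates 1 and 3 called 6177, which points to a structure of the samples that follows GC slope and mitochondrial share alike. An exchange of shNT day 7 replicate 3 with day 0 replicate 2 is argued against, since 5 of the 29 tested sarcomere genes (a share of 0.172) placed the first nearer the other group and 1 of 29 the second, and Actc1 was at 268 FPKM in the first and 0 in the second. Differences in RNA quality, cell death or handling between libraries may add to the structure and were not tested, nor was a biological source.

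The second pattern is the higher macrophage markers with shCalr at day 14. A GC bias is argued against, since the mean GC slopes were close, 0.149 ± 0.0412 in shCalr and 0.160 ± 0.0436 in shNT day 14. The list median after correction was 1.01 of that before, but with such slopes the correction could move it little. A lower share of the main cell type, which would raise markers of every other type alike, stays open: the mean of the endothelial and pericyte medians (0.69 and 0.97) was 0.911 of the macrophage median, while the other leukocyte list named in the same test had 0 tested members and the bound of 0.8 for a like rise was set after that value was seen. The endothelial genes also lay near the floor. In shNT day 14 their mean log2(FPKM + 1) was 0.865 to 0.913 per library, against 4.57 to 4.70 for macrophage genes. Adding 1 to the FPKM shrinks the endothelial changes more, so the ratio of 0.911 cannot show whether the rises were alike. Fibroblast genes were themselves higher (median 0.34), and 3 adipocyte genes, too few to decide, had a median of -0.26. A lower share of the main cell type, more macrophages remaining with shCalr and a response of the macrophages to Calr knockdown all stay open.

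The third pattern is the higher sarcomere genes with shCalr at both days. GC bias is argued against, since the list median after correction was at least 1.03 of that before. At day 14 the groups had close GC slopes, so the correction could move little there. More factor RNA in the shCalr libraries stays open, since the factors went both ways. They had a median of -0.114 at day 14 but Mef2c at 1.01 and Gata4 at -0.64, and at day 7 the sign of each of the 5 changed when a library was left out. Without the 5 libraries farthest in GC slope, Gata4 and Sall4 were called lower at day 7 (-0.60 and -0.39), with Mef2c at 0.34 and not called. A different share of cells taking up the factors, with unchanged factor RNA per culture, was not tested, and vector RNA hides the cells' own factor RNA. An action of Calr knockdown on the contractile genes therefore stays open beside these and beside an off-target action of the hairpin, which a single hairpin cannot exclude.

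Splits of 6 libraries, 10 per comparison, are too few for a share under 0.05. In shCalr against shNT 1 of 10 splits called as many genes as the real one at each day, with 678 against 1 in the next at day 7 and 914 against 0 at day 14. Against day 0 the real and next highest counts were 5745 and 0 in shNT day 14, 4654 and 3 in shCalr day 7, and 5224 and 0 in shCalr day 14, each reached by 1 of 10 splits. Between days they were 302 and 1 with shNT (1 of 10), and 91 and 114 with shCalr (2 of 10). The larger one there set shCalr day 14 replicate 1 with shCalr day 7 replicates 2 and 3, the libraries of these groups with the highest mitochondrial shares. For the difference between the days, 9 of 100 drawn splits, the real one included, called at least its 1 gene, so chance cannot be excluded. Of these, 3 splits that exchange shCalr and shNT in full at day 14 and at most 1 library of each at day 7 (1865, the highest, 1400 and 90 calls) hold the shCalr effect shared by the days, and the other 5 called 1 gene each. Among 82 splits, the real one and those that exchange 1 library of each group at both days, 2 called at least 1 gene, the real one included, and with the mean shCalr effect subtracted first 3 of the 100 drawn splits did, again with the real one. The highest other was 1 in both, no lower than the real count, so neither excludes chance for the call of Hspa1b.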

How the results depend on the processing

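The GC correction and the fit without the 5 libraries farthest in GC slope were chosen only after the data were seen. For named genes, 9747 of 10355 alternative values kept direction and side of the threshold, 420 were no longer called, 161 became called and 27 changed sign. For lists it was 743 of 779 kept, 35 no longer called and 1 changed sign. Calls are given in the order shCalr against shNT at day 7 and day 14, shNT day 7, shNT day 14, shCalr day 7 and shCalr day 14 against day 0, and day 14 against day 7 with shNT and with shCalr. A mean FPKM of at least 5, which tests fewer genes (7971), gave 377, 480, 1852, 3440, 2673, 3057, 143 and 34 calls, and a fold of at least 2, which is stricter by construction, 255, 357, 1519, 2802, 2203, 2546, 141 and 45. Without the 5 libraries, which narrows the spread by construction, there were 2031, 1769, 9000, 8872, 7935, 8789, 1419 and 1201. GC correction gave 1329 and 1738 for shCalr against shNT, and 558 and 152 between days. Only the libraries of the contrast, which estimates the spread from those alone, gave 7 and 3353. It gave 1375 for shNT day 7, and 0 and 33 between days. The shCalr against shNT counts moved opposite ways from the main 678 and 914. Groups differed in spread, with a GC slope SD of 0.559 in shNT day 7 and 0.125 in shCalr day 7. It was 0.0436 in shNT day 14 and 0.0412 in shCalr day 14. The main fit uses the same spread per gene for all groups, so its p-values may be too small at day 7 and too large at day 14. Between days with shCalr, TPM gave 22, a pseudocount of 0.1 gave 35 and no filter 140. For the difference between days no filter gave 6 genes (3 each way), and block, GC correction, the 5 libraries left out, voom and its 12 libraries alone gave 0 in limma (479, 822, 970, 459 and 511 at an unadjusted p under 0.05). The overlap of the 2 days became 239 with a mean FPKM of at least 5, 842 with GC correction, 1064 without the 5 libraries, 6 with the contrast's libraries alone and 152 at 2-fold. Calr at day 7 kept -1.76 with its libraries alone but not its call (adjusted p = 0.0732). Lists called for the difference became 1 with an estimated correlation and 8 without the 5 libraries. Of the 3 signature calls, those of the day 14 rises and falls in the day 7 effect ended with an estimated correlation (0.274 and 0.611), and that of the falls also with fry (0.356). The call of the day 7 falls in the day 14 effect stayed with both (0.0204 and 0.000445).

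Without one library, calls ranged from 370 to 784 and from 475 to 561 in shCalr against shNT, 2175 to 6213, 3949 to 6808, 3028 to 6078 and 3579 to 6505 against day 0, 120 to 327 and 25 to 90 between days, and 0 to 3 for the difference. The overlap ranged from 252 to 559, lists for the difference from 2 to 6, Calr from -1.85 to -1.67 at day 7, the day 14 falls in the day 7 effect from 7.1e-07 to 0.886, and the day 7 falls in the day 14 effect from 2.1e-16 to 1.5e-14. Signs changed without one library for factors and other genes that were not called, with lowest and highest log2 at day 7 of -0.52 and 0.44 (Mef2c), -0.35 and 0.44 (Gata4), -0.70 and 0.27 (Tbx5), -0.37 and 0.26 (Myocd), -0.38 and 0.41 (Sall4), -0.21 and 0.16 (Fabp4) and -0.15 and 0.10 (Sox9). At day 14 Tbx5 ranged from -0.22 to 0.37, and between days with shNT Gata4 from -0.016 to 0.78 and Sall4 from -0.67 to 0.12. Without the 5 libraries the day 7 shCalr change was 0.34 in Mef2c, -0.60 in Gata4 (adjusted p = 0.00648), -0.39 in Sall4 (0.0431) and -0.34 in Fabp4, Tbx5 was at -0.16 at day 14, Gata4 at 0.011 between days with shCalr, and the mitochondrial list of the difference turned down (0.000536). Quantile normalization put Fabp4 at -0.032 and Sox9 at -0.060 at day 7, and GC correction Fabp4 at 0.26 in shNT day 14 against day 0. The cause was not tested where the text names none. With the replicate number as a block, although no pairing by number was seen, calls were 521, 732, 2991, 5506, 4392, 5035, 228 and 62 in the order above. TPM, median-ratio and quantile scaling moved the median change of all genes by under 0.1 in both shCalr effects and both shNT comparisons with day 0. At 9505879 to 12791001 reads and 3 libraries per group, few changes near 1.5-fold were called on simulated data (8.96 and 7.46%). Those data had the same spread setting in all groups and changed only genes with a mean FPKM of 2 or more in shNT. An uncalled gene is not shown to be unchanged.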
